A study of Mus musculus with 26 samples.

How the data were processed

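RNA was measured by sequencing in 26 libraries from whole mouse brain: 12 of sorted nuclei, 12 of presort nuclei, which are nuclei taken before the sort, and 2 of cytoplasm. RNA was extracted with Trizol, treated with DNase, purified on Qiagen MinElute columns and amplified with the NuGEN Ovation RNA-seq V2 kit, per the labels' protocols. Trimmomatic, Bowtie2, STAR, bedtools and edgeR were used by the authors, per the submitters' processing notes, which give neither their versions nor their order. The authors deposited 1 table of raw counts per gene and library, with 27501 Ensembl gene identifiers, an entry named GFP and 1 column for each of the 26 libraries. Every value was a whole number, and no normalization had been applied. The genome build, the annotation, the regions counted and the strand setting behind these counts are not given in the sources used here, nor is the method of sorting. The kit keeps no strand, so counts of overlapping genes could not be separated by strand. The kit as described adds no molecular identifiers, so counts are reads and not molecules, and all intervals and floors cover counting error only.

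Gene symbols and biotypes came from GENCODE M21 (GRCm38), in which 26495 identifiers were found and 1006 were not. Coordinates are those of GENCODE M21 for the same identifier. In all, 6450 genes had 0 counts in every library. Groups were taken from the sample titles and characteristics. The 3 mouse lines carried a fusion of green fluorescent protein with Rpl10a under the control of Snap25 (neuron line), Aldh1l1 (astrocyte line) or Cnp (oligodendrocyte line). Each nuclear group held 4 libraries, 2 from females and 2 from males, and the replicates are independent mice, per the design text. Replicate numbers are those in the sample titles. Males had numbers from 1 to 12 and females from 25 to 36, so sex and the block of numbers coincide. The cytoplasmic libraries came from whole brain but carry a cell type label, which was not used. Total counts ranged from 134357 to 4461568 per library, and a floor of 3 counts corresponded to between 0.672 and 22.3 CPM. No 2 replicates were copies of each other, since the chi-square per degree of freedom between replicates was at least 2.15.

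The comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM normalization and the filterByExpr filter (minimum count 10) by group. All tests were two-sided, and p-values were adjusted with the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. Standard errors were derived from the log2 fold change and the F statistic. The 3 sorted types were compared in 1 fit of 12 libraries. A gene counted as enriched in a type when its adjusted p passed and its log2 fold change exceeded 1 against each of the other types. Sorted and presort nuclei were compared within each line in a fit of its 8 libraries, and the 12 presort libraries were compared with the 2 cytoplasmic ones. Sex was tested in the 12 sorted libraries with cell type as a covariate and in the 12 presort libraries with line as a covariate. The interaction of sex and cell type and the differences among lines in presort nuclei were tested jointly over their coefficients.

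A total of 28 gene lists were used: pan-neuronal, glutamatergic, GABAergic, modulatory neuron, cerebellar granule cell, astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia, endothelial, mural and fibroblast, ependymal and choroid plexus, and blood markers; astrocyte, oligodendrocyte and neuronal transcription factors; nuclear long noncoding RNAs (lncRNAs), host-gene lncRNAs, mitochondrially encoded, ribosomal protein, nuclear-encoded respiratory, long synaptic, immediate early, cholesterol synthesis, splicing factor, gliosis, Y-linked and X-escape genes. None was chosen by the study. Lists share members: 5 of the 27 oligodendrocyte markers, 6 of the 12 oligodendrocyte transcription factors, 4 of the 16 glutamatergic markers, 4 of the 18 neuronal transcription factors and 2 of the 27 astrocyte markers stand in another list, and at most 1 member of any other list does. Of 17 nuclear lncRNA names 8 were in the table. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of the comparison, and again with a correlation estimated per list, with ranks, and with fry. Camera compares a list with the other genes, whereas fry asks whether a list moves on balance one way. The modulatory neuron list had 1 tested member among the sorted libraries and was not tested.

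Named genes followed a rule: the drivers Snap25, Aldh1l1 and Cnp with Rpl10a; the 6 largest fold changes in each direction among genes that passed, whose groups did not overlap and whose mean was at least 10 CPM in the higher group, leaving out unnamed gene models; up to 4 members that passed and 2 that did not from each list described; and for sex and line up to 15 genes by smallest p with 5 sex-linked genes. GFP was added to the drivers after the table was opened. Some genes that the rule named are not reported here. Means and SDs per group are normalized CPM. A fold against a group with 0 counts is given as a lower bound against 3 counts over the group, and with 1 to 3 counts as a ratio with an exact 95% counting interval.

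The design text says that each mouse gave a presort control. That neighbouring numbers, such as 1 and 2, are 1 mouse was inferred and was checked on log2 CPM after the mean of each group was removed, by correlating sorted with presort libraries across genes, which are not independent replicates. In the neuron line the 4 pairs correlated across 4275 genes with values from 0.368 to 0.527, against 0.161 to 0.408 for the other libraries of the same sex. In the astrocyte line the pairs ranged from 0.08 to 0.284, with 3 above 0.1, and in the oligodendrocyte line from -0.016 to 0.197, with 2 above 0.1. In each of the 3 lines 3 of 4 sorted libraries correlated best with their own partner. Gene lists were tested with the block only where every pair correlated above 0.1, which held in the neuron line.

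The steps were tested on simulated counts drawn from the real means, library sizes and dispersions, with changes of 2, 4, 16 and 64-fold. For neurons against astrocytes 2%, 12.2%, 91.7% and 97.9% were recovered among 12758 genes. Without sorted oligodendrocyte replicate 36 the shares were 10%, 87.2%, 100% and 100% among 13198 genes. Sorted against presort nuclei gave 20%, 77.3%, 100% and 100% among 10419 genes in the neuron, 20.4%, 84.1%, 100% and 100% among 10483 in the astrocyte, and 3.1%, 0%, 91.9% and 100% among 7013 in the oligodendrocyte line. Presort nuclei against cytoplasm gave 12.8%, 85%, 100% and 100% among 7220 genes. The sex comparison gave 2%, 25.5%, 100% and 100% among 12742 genes in sorted and 52.4%, 97.8%, 100% and 100% among 5668 in presort nuclei. The interaction gave 0%, 0%, 6.4% and 43.8% among 12773 genes, and the lines gave 22.9%, 95.9%, 100% and 100% among 5684 genes. Of 100 unchanged simulated lists per comparison, between 0 and 2 passed an unadjusted p of 0.05 in camera. Genes were simulated independently, so this cannot show how camera behaves for lists whose genes vary together.

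Alternatives were DESeq2 1.42.0 with its own size factors, RLE size factors in edgeR, no filter on low counts, thinning to the smallest library, sex as a covariate, a fit of all 24 nuclear libraries, the replicate block, sorted nuclei or a part of the presort nuclei against cytoplasm, and leaving out each replicate in turn. Fits of each sex alone, of the presort libraries of each sex against cytoplasm, and without 3 libraries that stood apart in depth or genes detected, gene lists without each cytoplasmic library or without Xist, and count bounds without each library, were added after seeing the data. No library was left out of the main comparisons. Figures, permutation tests and summaries were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.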

Results

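RNA was counted per gene in 26 libraries from whole brains of mice aged 6 to 12 weeks, to ask which nuclear RNAs differ among neurons, astrocytes and oligodendrocytes. In 3 transgenic lines a fusion of green fluorescent protein (GFP) with the ribosomal protein Rpl10a was expressed under the control of Snap25, a neuronal gene, Aldh1l1, an astrocyte gene, or Cnp, an oligodendrocyte gene. Nuclei were sequenced after sorting (sorted neuron, astrocyte and oligodendrocyte nuclei) and before it (presort nuclei of each line, a mixture of cell types), with 4 libraries in each of these groups, 2 from females and 2 from males. A further 2 libraries held whole-brain cytoplasm. Sorted libraries held 134357 to 3239445 counts (median 2485416.5), presort libraries 147826 to 3274488 (median 260451), and the cytoplasmic libraries 4461568 and 3885312. Presort astrocyte-line replicate 29 was the deepest presort library, and sorted astrocyte replicate 30, with 134357 counts and 11136 genes detected, the shallowest sorted one. Sorted oligodendrocyte replicate 36 had 1602594 counts but only 7674 genes detected, against 16223 to 16575 in the other 3 libraries of its group, and 0 GFP counts. In GENCODE M21 (GRCm38), Snap25 lies on chromosome 2 from 136713453 to 136782428, Aldh1l1 on chromosome 6 from 90486427 to 90600203, Cnp on chromosome 11 from 100574904 to 100591729 and Rpl10a on chromosome 17 from 28328471 to 28331033.

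**Figure D1:**
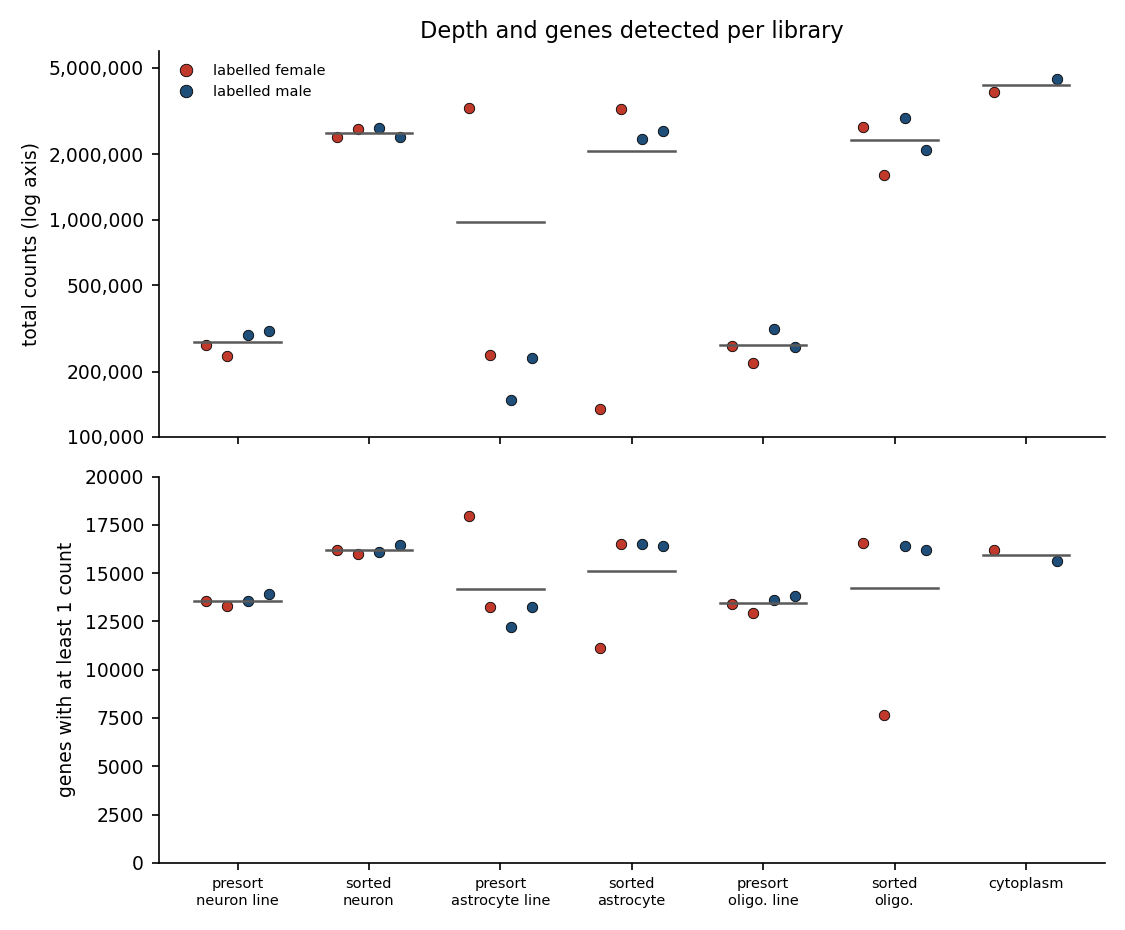
Total counts (log axis) and genes with at least 1 count in each of the 26 libraries by group, with the group mean as a line and colour for the sex label. Presort astrocyte-line replicate 29 (3274488 counts), sorted astrocyte replicate 30 (134357 counts) and sorted oligodendrocyte replicate 36 (7674 genes) stood apart from their groups.

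Sorted neuron nuclei differed from sorted astrocyte nuclei in genes of both cell types. All 27 tested astrocyte markers were lower in neurons, with a median log2 fold change of -5.31 (camera adjusted p = 5.85e-28). Fgfr3, a fibroblast growth factor receptor, was at 19.3 ± 6.87 CPM in neurons and 2321 ± 379 CPM in astrocytes (SD, n = 4 each). Its log2 fold change was -6.91 ± 0.60 (SE, adjusted p = 2.3e-06). Others were Gjb6, the gap junction protein connexin 30 (-6.53 ± 0.89, adjusted p = 8.29e-05), and Itih3 (-7.43 ± 0.87, adjusted p = 2.41e-05). Of 15 astrocyte transcription factors 13 were lower (14 adjusted over the list alone, median -4.61, camera adjusted p = 2.11e-12). They included Hes5, a target of Notch signalling (-6.91 ± 1.02), and Id3 (-5.73 ± 0.83). Cerebellar granule cell markers were higher in neurons in 8 of 10 cases (8 adjusted over the list alone, median 3.74, camera adjusted p = 1.91e-07). Cbln3 was at 4328 ± 1374 against 83.2 ± 9.56 CPM (log2 fold change 5.69 ± 0.40, adjusted p = 8.61e-07), and Gabra6, a GABA receptor subunit of granule cells (5.52 ± 0.57), rose as well. The granule cell list had adjusted p = 0.0753 with an estimated correlation. Pan-neuronal markers were higher in 12 of 25 cases (13 adjusted over the list alone, camera adjusted p = 1.2e-06). Among them were Syt1, a calcium sensor of synaptic vesicles (3.73 ± 0.36), Rbfox3 (3.75 ± 0.67) and Snap25 (2.79 ± 0.50, adjusted p = 0.000771). The pan-neuronal list had adjusted p = 0.287 with an estimated correlation.

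Further neuronal lists were higher in neurons than in astrocytes. Glutamatergic markers were higher in 6 of 15 cases (9 adjusted over the list alone, camera adjusted p = 0.000215), including the NMDA receptor subunit Grin1 (log2 fold change 4.53 ± 0.81) and Neurod1 (4.37 ± 0.76). The glutamatergic list had adjusted p = 0.219 with an estimated correlation. Long synaptic genes were higher in 12 and lower in 2 of 23 cases (14 and 2 adjusted over the list alone, camera adjusted p = 0.000111), including Csmd3 (3.84 ± 0.42) and Opcml (3.64 ± 0.51). The long synaptic list had adjusted p = 0.163 with an estimated correlation. GABAergic markers were higher in 4 and lower in 1 of 10 cases (5 and 1 adjusted over the list alone, camera adjusted p = 0.0188), and Reln rose (4.06 ± 0.55). The GABAergic list had adjusted p = 0.127 with an estimated correlation. Immediate early genes were higher in 5 of 10 cases (6 adjusted over the list alone, camera adjusted p = 0.0036). The immediate early list had adjusted p = 0.219 with an estimated correlation. Among 8 nuclear lncRNAs, Rian (4.24 ± 0.48), Mirg (4.63 ± 0.76), Snhg11 (4.04 ± 0.46) and 1 other were higher. Neat1, the scaffold of paraspeckles (-6.61 ± 0.54), and 1 other were lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.0743). The ribosomal protein list moved up by camera (median 0.65, adjusted p = 0.0024), although 0 of its 77 genes passed over all genes or over the list alone by edgeR (1 by DESeq2). The ribosomal protein list had adjusted p = 0.603 with an estimated correlation. Lower in neurons were 5 of 6 ependymal and choroid plexus markers (6 adjusted over the list alone, camera adjusted p = 9.58e-06 and adjusted p = 0.127 with an estimated correlation), such as Ttr, the thyroid hormone carrier of the choroid plexus (-6.23 ± 0.69). Also lower were 6 of 8 mural and fibroblast markers (7 adjusted over the list alone, camera adjusted p = 0.000131 and adjusted p = 0.219 with an estimated correlation), such as Pdgfrb (-7.23 ± 0.87). Gliosis genes were lower in 5 of 6 cases (6 adjusted over the list alone, camera adjusted p = 0.000215 and adjusted p = 0.124 with an estimated correlation), such as Gfap, an astrocyte filament protein (-4.07 ± 0.64).

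By edgeR, 1045 genes were higher and 1489 lower in neurons than in astrocytes of 13029 tested. The groups did not overlap in 4436 of all tested genes (34%), which chance gives for 2.86% of genes. Among the largest rises were those of Ntf3, the neurotrophin-3 gene, at least 38.3-fold against 0 astrocyte counts (24.1-fold without sorted astrocyte replicate 32), and of Crtam (log2 fold change 6.38 ± 0.75) and Ptchd1 (6.10 ± 0.79). The largest falls, against 0 neuron counts, were at least 188-fold for Gli1, a transcription factor of hedgehog signalling, 162-fold for Oaf, 173-fold for Slc2a10, 153-fold for Pm20d1 and 107-fold for Aqp9, a water and glycerol channel. Aldh1l1 fell (-5.72 ± 0.65, adjusted p = 1.77e-05). Cnp (-0.61 ± 0.35, adjusted p = 0.277), Rpl10a (-0.27 ± 0.65, adjusted p = 0.853) and GFP (-0.30 ± 0.68, adjusted p = 0.842, and 0.10 without sorted astrocyte replicate 6) did not pass. In males alone 1627 genes were higher and 1989 lower, and in females alone 8 and 38. Without sorted oligodendrocyte replicate 36, which shares the estimate of spread, 2299 were higher and 2797 lower, and 684 were higher without sorted astrocyte replicate 6.

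**Figure D2:**
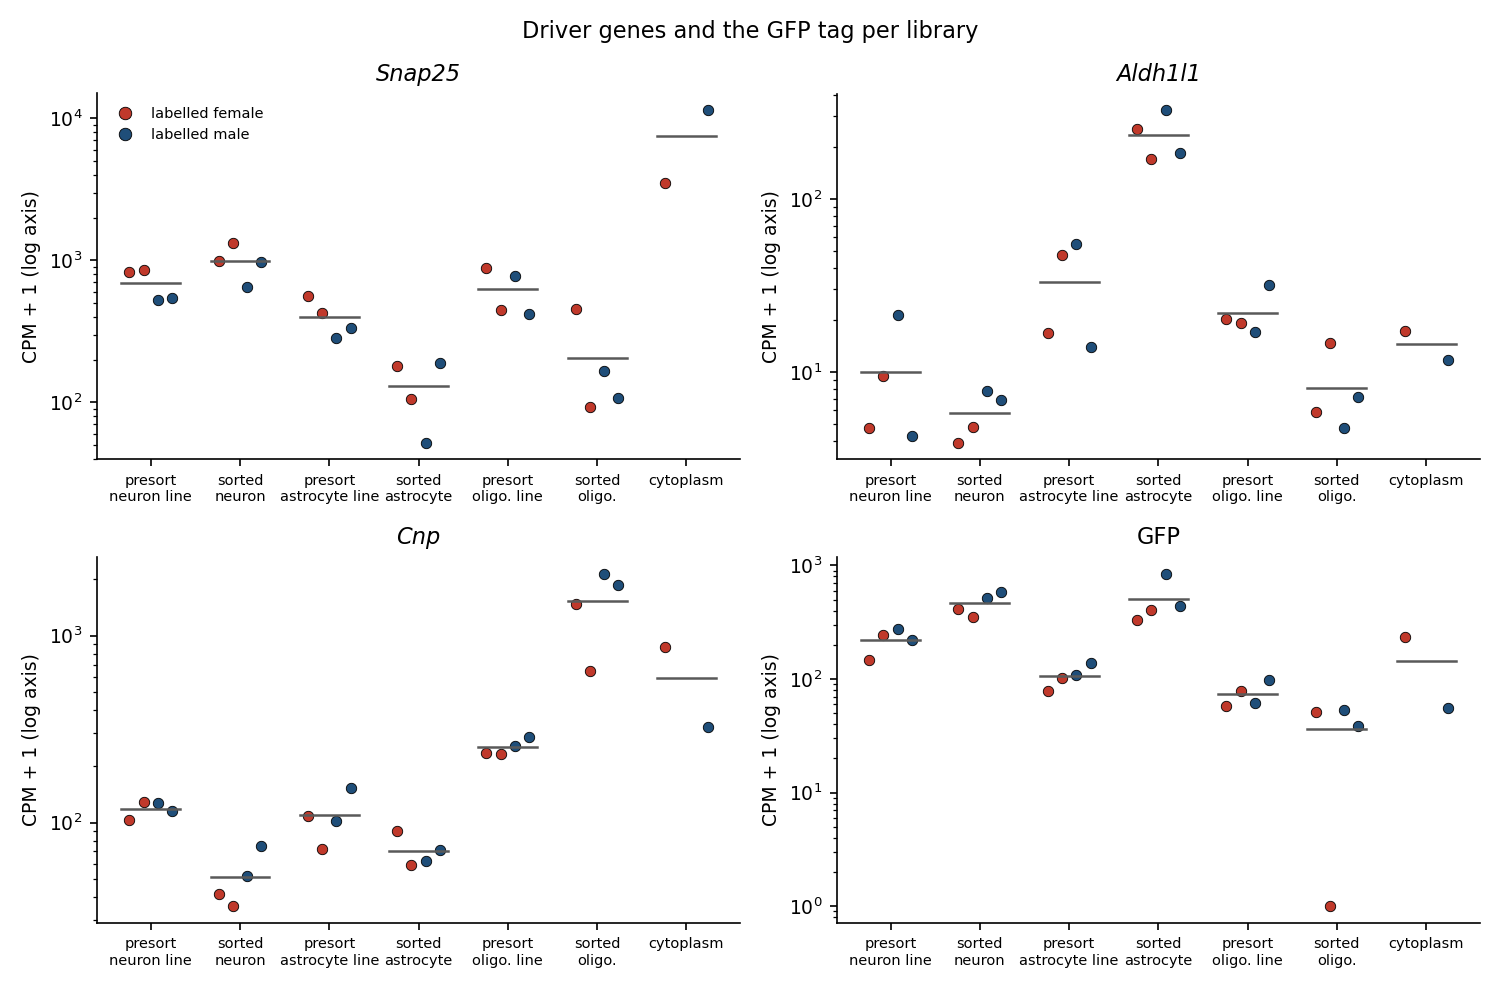
Snap25, Aldh1l1, Cnp and GFP in each library as CPM plus 1 on a log axis, with the group mean as a line and colour for the sex label, so that the value of 0 for GFP in sorted oligodendrocyte replicate 36 is drawn at 1. Aldh1l1 was highest in the 4 sorted astrocyte libraries, and Cnp had its highest mean in sorted oligodendrocyte nuclei.

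Against sorted oligodendrocyte nuclei, neurons were lower in all 24 tested oligodendrocyte markers (24 adjusted over the list alone, median log2 fold change -6.64, camera adjusted p = 3.55e-40). The myelin genes Mag (4.48 ± 2.19 against 972.8 ± 113 CPM, SD, n = 4 each, log2 fold change -7.75 ± 0.48, SE, adjusted p = 9.51e-08), Mobp (-7.20 ± 0.52, adjusted p = 1.77e-07) and Opalin (-7.44 ± 0.78, adjusted p = 5.87e-06) were among them, as was Hapln2 (-7.89 ± 0.82). Of 11 oligodendrocyte transcription factors 10 were lower (11 adjusted over the list alone, camera adjusted p = 2.95e-11), with Myrf, a regulator of myelin genes, at -7.15 ± 0.69, Sox10 at -6.81 ± 0.82 and Olig1 at -6.03 ± 0.55. Neat1 was 368-fold lower in neurons (12.1 ± 5.05 against 4462 ± 3175 CPM, -8.52 ± 0.58, adjusted p = 1.62e-07), and Rian was higher (3.86 ± 0.47). The nuclear lncRNA list as a whole did not pass (4 higher and 2 lower of 8, also adjusted over the list alone, camera adjusted p = 0.548). Zeb2, a neuronal transcription factor by its list, was lower in neurons (-3.80 ± 0.36), against 6 of the 18 in that list that were higher (6 adjusted over the list alone, camera adjusted p = 0.0165). The neuronal factor list had adjusted p = 0.559 with an estimated correlation.

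Cerebellar granule cell markers were higher in neurons than in oligodendrocytes in 9 of 10 cases (10 adjusted over the list alone, camera adjusted p = 9.7e-08), including Gabra6 (log2 fold change 5.63 ± 0.56), Cbln1 (5.43 ± 0.68) and Cbln3 (5.22 ± 0.39). The granule cell list had adjusted p = 0.0674 with an estimated correlation. Higher too were 13 of 25 pan-neuronal markers (15 adjusted over the list alone, camera adjusted p = 0.000207 and adjusted p = 0.533 with an estimated correlation), such as Syt1 (3.13 ± 0.35). Glutamatergic markers were higher in 8 of 15 cases (8 adjusted over the list alone, camera adjusted p = 0.00285 and adjusted p = 0.427 with an estimated correlation), such as Grin1 (3.51 ± 0.76) and Neurod1 (4.57 ± 0.75). Of the immediate early genes 5 of 10 were higher (5 adjusted over the list alone, camera adjusted p = 0.0165), including Npas4 (4.21 ± 0.87) and Btg2 (3.06 ± 0.59). The immediate early list had adjusted p = 0.427 with an estimated correlation. Among 65 nuclear-encoded respiratory genes 7 were higher and 1 lower (0 adjusted over the list alone, camera adjusted p = 0.000275), with Cox4i1 at 2.27 ± 0.65 (adjusted p = 0.0175). The respiratory list had adjusted p = 0.533 with an estimated correlation. Splicing factors were lower in 6 of 24 cases (8 adjusted over the list alone, camera adjusted p = 0.0156), such as Srrm2 (-1.37 ± 0.35). The splicing factor list had adjusted p = 0.427 with an estimated correlation.

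Neurons had 1395 genes higher and 1610 lower than oligodendrocytes by edgeR (3776 of all tested genes not overlapping, 29%, against 2.86% by chance). With DESeq2 2288 were higher and 1731 lower, a change from 46.4% to 56.9% higher, whereas RLE size factors in edgeR gave 49.7%. Crtam (log2 fold change 5.64 ± 0.69) and Gabra6 were among the 6 genes with the largest rises. The largest falls against 0 neuron counts were at least 197-fold for Cldn14, 182-fold for Sh3tc2, 190-fold for Ankub1 and 116-fold for Itgad. Without sorted oligodendrocyte replicate 36 the bounds were 51.9-fold for Cldn14 and 48.2-fold for Itgad. Cnp fell (-5.28 ± 0.40, adjusted p = 2.23e-07). Snap25 (1.94 ± 0.48, adjusted p = 0.00787), Rpl10a (2.50 ± 0.69, adjusted p = 0.015) and GFP (3.45 ± 0.75, adjusted p = 0.00339) were higher in neurons. Aldh1l1 did not pass (-1.05 ± 0.58, adjusted p = 0.216, and 0.08 in males alone). Males alone gave 1840 higher and 1933 lower genes, and females alone 9 and 114. Without sorted oligodendrocyte replicate 36 the counts were 2263 and 2544.

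Astrocyte and oligodendrocyte nuclei differed in the marker lists of each type. Astrocyte markers were higher in astrocytes in 25 of 27 cases (26 adjusted over the list alone, median log2 fold change 4.96, camera adjusted p = 5.68e-22). Among them were Slc7a10, an amino acid transporter (6.98 ± 0.60, SE, adjusted p = 1.18e-06), Fgfr3 (6.61 ± 0.59, adjusted p = 1.32e-06), Ntsr2 (6.59 ± 0.61, adjusted p = 1.8e-06) and Agt, the angiotensinogen gene (6.16 ± 0.68, adjusted p = 1.01e-05). Oligodendrocyte markers were lower in 23 of 24 cases (23 adjusted over the list alone, median -5.80, camera adjusted p = 1.26e-33), with Opalin (-7.73 ± 0.85), Sox10 (-7.29 ± 0.89) and Fa2h, an enzyme of myelin lipid synthesis (-7.14 ± 0.69). Transcription factors followed, with 11 of 15 astrocyte factors higher (12 adjusted over the list alone, camera adjusted p = 5.6e-08), such as Rfx4 (6.40 ± 0.68) and Hes5 (6.44 ± 1.01). Of the oligodendrocyte factors 6 of 11 were lower (7 adjusted over the list alone, camera adjusted p = 2.93e-07), such as Myrf (-6.66 ± 0.71) and St18 (-5.88 ± 0.44). Ependymal and choroid plexus markers were higher in astrocyte nuclei in 5 of 6 cases (5 adjusted over the list alone, camera adjusted p = 0.000166). Ttr was at 4324 ± 2721 against 82.9 ± 32.9 CPM (SD, n = 4 each), and Otx2, a transcription factor, had a log2 fold change of 6.08 ± 0.78. The ependymal list had adjusted p = 0.278 with an estimated correlation. Gliosis genes were higher in 4 of 6 cases (4 adjusted over the list alone, camera adjusted p = 0.0174), such as Gfap (3.23 ± 0.62) and Cd44 (3.82 ± 0.90). The gliosis list had adjusted p = 0.338 with an estimated correlation. Long synaptic genes went both ways, 4 higher and 5 lower of 23 (5 and 9 adjusted over the list alone, camera adjusted p = 0.538). Lsamp (4.04 ± 0.35) was higher in astrocytes, and Ptprd (-3.76 ± 0.29) and Csmd3 (-3.71 ± 0.42) were higher in oligodendrocytes. Of the oligodendrocyte precursor markers Ptprz1 was higher in astrocytes (4.91 ± 0.46) and Gpr17 lower (-3.90 ± 0.63), in a list with 4 higher and 1 lower of 11 (4 and 1 adjusted over the list alone, camera adjusted p = 0.152).

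Astrocytes had 1254 genes higher and 976 lower than oligodendrocytes by edgeR (2862 of all tested genes not overlapping, 22%, against 2.86% by chance). Among the largest rises were those of Cyp4f15 (log2 fold change 7.61 ± 0.72) and of Ttpa, the vitamin E transfer protein gene, at least 56.1-fold against 0 counts (37.3-fold without sorted oligodendrocyte replicate 10). Among the largest falls were those of Itgad and Sp7, a transcription factor, at least 82.1-fold and 45.1-fold. Without sorted astrocyte replicate 32 these bounds were 50.9-fold and 28-fold, and that of Itgad was 33.9-fold without sorted oligodendrocyte replicate 36. Nat8f6, Speer4a and Speer4c met the same criteria but have close paralogs, so their counts are uncertain. GFP (3.75 ± 0.76, adjusted p = 0.00203) and Rpl10a (2.77 ± 0.70, adjusted p = 0.0101) were higher in astrocytes, as was Aldh1l1 (4.68 ± 0.62, adjusted p = 5.76e-05). Cnp was lower (-4.66 ± 0.40, adjusted p = 1.02e-06) and Snap25 did not pass (-0.85 ± 0.47, adjusted p = 0.271). In males alone 1649 genes were higher and 1374 lower, in females alone 17 and 50, and without sorted oligodendrocyte replicate 36 1980 and 1588. In a fit of all 24 nuclear libraries the balance turned, with 1479 higher and 1834 lower. With an estimated correlation, the calls of the astrocyte and astrocyte transcription factor lists held in both comparisons with astrocytes, at adjusted p from 0.00151 to 0.0195. Those of the oligodendrocyte and oligodendrocyte transcription factor lists held in both comparisons with oligodendrocytes, from 0.000106 to 0.0189.

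Enriched genes numbered 679 in neurons, 758 in astrocytes and 698 in oligodendrocytes, and every library of the type lay above every other library in 1279, 1160 and 696 of all tested genes (9.82%, 8.9% and 5.34%), which chance gives for 0.202% of genes. Neuron-enriched genes held 11 of 25 pan-neuronal markers, 7 of 10 cerebellar granule cell markers, 9 of 23 long synaptic genes and 4 of 8 nuclear lncRNAs (Meg3, Mirg, Rian and Snhg11). The 6 that ranked first were Xkr7, Crtam, Ntf3, Gabra6, Cbln1 and Ptchd1, with Gabra6 at 1023 ± 366 CPM against 23.6 ± 13.9 in astrocytes and 20.6 ± 10.1 in oligodendrocytes (SD, n = 4 each). Astrocyte-enriched genes held 25 of 27 astrocyte markers, 10 of 15 astrocyte transcription factors and 4 of 6 ependymal and choroid plexus markers (Folr1, Clic6, Kl and Ttr), and Nat8, Cyp4f15, Celrr, Eva1a, Tmem72 and Aqp9 ranked first. Eva1a had 70.4 ± 36.8 CPM in astrocytes and 0.527 ± 0.458 and 0.449 ± 0.444 in neurons and oligodendrocytes. Oligodendrocyte-enriched genes held 23 of 24 oligodendrocyte markers, Neat1, and the long synaptic genes Ptprd and Lrp1b. Itgad, Galnt5, Fbxw15, Sp7, Tex52 and Galnt6 ranked first. Itgad (49.3 ± 74 CPM), Fbxw15 (22.9 ± 28.5) and Sp7 had 0 CPM in both other types, so their fitted folds and ranks are uncertain. Of lncRNA genes 35 of 429 were neuron-enriched (8.16%), against 626 of 12254 protein-coding genes (5.11%; two-sided Fisher's exact test, odds ratio 1.65, p = 0.00779), whereas the odds ratios were 0.99 (p = 1) in astrocytes and 0.995 (p = 1) in oligodendrocytes. In males alone 988, 1020 and 894 genes were enriched in neurons, astrocytes and oligodendrocytes, and in females alone 6, 9 and 32. Without sorted oligodendrocyte replicate 36 the neuron count was 1247 and the astrocyte count 1282, and DESeq2 gave 1031 for neurons.

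Sorting of the neuron line lowered the RNA of other cell types more than it raised that of neurons. All 24 oligodendrocyte markers fell relative to presort nuclei (24 adjusted over the list alone, median log2 fold change -3.22, camera adjusted p = 1.93e-31). Mag was at 5.34 ± 2.49 against 94.2 ± 25.3 CPM (SD, n = 4 each, log2 fold change -4.12 ± 0.40, SE, adjusted p = 1.37e-05), and Gjc3 fell too (-3.89 ± 0.39). Markers of other types fell as well, 9 of 10 for oligodendrocyte precursors (10 adjusted over the list alone, camera adjusted p = 5.16e-14), with Gpr17 (-4.42 ± 0.36) and Pdgfra (-3.94 ± 0.34). Astrocyte markers fell in 18 of 26 cases (21 adjusted over the list alone, camera adjusted p = 4.01e-18), with Gjb6 at -3.66 ± 0.49. For microglia the count was 8 of 12 (11 adjusted over the list alone, camera adjusted p = 3.34e-12), with Siglech at -4.48 ± 0.58. Endothelial markers fell in 5 of 6 cases (5 adjusted over the list alone, camera adjusted p = 4.97e-08), with Flt1 at -4.29 ± 0.69. Mural and fibroblast markers fell in 7 of 7 (7 adjusted over the list alone, camera adjusted p = 2.52e-11), with Rgs5 at -4.82 ± 0.65. The calls of these lists held with an estimated correlation at adjusted p from 0.00289 to 0.0305, and that of the astrocyte transcription factors (3 of 9 lower, 1 higher and 4 lower adjusted over the list alone) at 0.0486. With neighbouring numbers as a block these 7 calls were lost with an estimated correlation, at adjusted p from 0.106 to 0.131, and passed with the preset one. Granule cell markers rose in 3 of 10 cases (5 adjusted over the list alone, camera adjusted p = 0.00401), or 6 with the block. Gabra6 was at 1.48 ± 0.32 (adjusted p = 0.00992) and Neurod1 at 1.17 ± 0.26 (adjusted p = 0.0128). Long synaptic genes rose in 5 of 23 cases (9 adjusted over the list alone, camera adjusted p = 1.18e-05), or 11 with the block. Grik2 (1.14 ± 0.21) and Ctnna2 (1.21 ± 0.27) rose. The lncRNAs Neat1 (-4.50 ± 0.37), Miat (-1.84 ± 0.32) and Meg3 (-1.05 ± 0.18) fell, 3 of 8 in that list (3 adjusted over the list alone, camera adjusted p = 0.0277). The lncRNA list had adjusted p = 0.219 with an estimated correlation. Pan-neuronal markers had a median of 0.25 and did not pass as a list (camera adjusted p = 0.0577). Of 25 genes 1 was higher (1 adjusted over the list alone). With the block 5 were higher and 1 lower (camera adjusted p = 0.0605). Syt1 rose (0.94 ± 0.21, adjusted p = 0.0128), but not without sorted neuron replicate 28 (adjusted p = 0.0651).

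In the neuron line 140 genes were higher and 562 lower in sorted than in presort nuclei of 11024 tested by edgeR (1545 of all tested genes not overlapping, 14%, against 2.86% by chance), and with neighbouring numbers as a block 546 and 904. Sex as a covariate gave 408 and 758, and a fit of all 24 nuclear libraries 17 and 535. Under the block the mitochondrially encoded list passed (3 lower of 8, camera adjusted p = 0.000852), which it did not without it (0 lower, adjusted p = 0.134). With an estimated correlation that list had adjusted p = 0.371. Among the largest falls were those of the transporter genes Slc22a8 (log2 fold change -6.70 ± 0.64) and Slco2b1 (-5.93 ± 0.84), and of Cdh1, the E-cadherin gene (-5.87 ± 0.71). The largest rises, Slc35f4, Samd12, Gcdh, Rasgef1b, Pms1 and Muc15, rested on 3 to 10 presort counts, and each was called in only 1 or 2 of the 4 refits that left out a presort library and still tested it. GFP rose 2.27-fold (1.19 ± 0.25, adjusted p = 0.00848). Rpl10a (0.66 ± 0.23, adjusted p = 0.11) and Snap25 (0.63 ± 0.26, adjusted p = 0.191) did not pass, the latter passing without sorted neuron replicate 2 (0.71). Cnp fell (-1.12 ± 0.29, adjusted p = 0.029), a call lost in 6 of 8 refits that left out 1 library. Males alone gave 0 higher and 127 lower genes by edgeR (1243 with unadjusted p under 0.05) and females alone 241 and 554. The count of higher genes fell to 73, 66 and 90 without presort replicates 25, 27 and 3 and to 45, 49 and 80 without sorted replicates 26, 28 and 4, and was 262 without sorted replicate 2. The count of lower genes was 297, 302 and 314 without sorted replicates 26, 28 and 4.

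**Figure D3:**
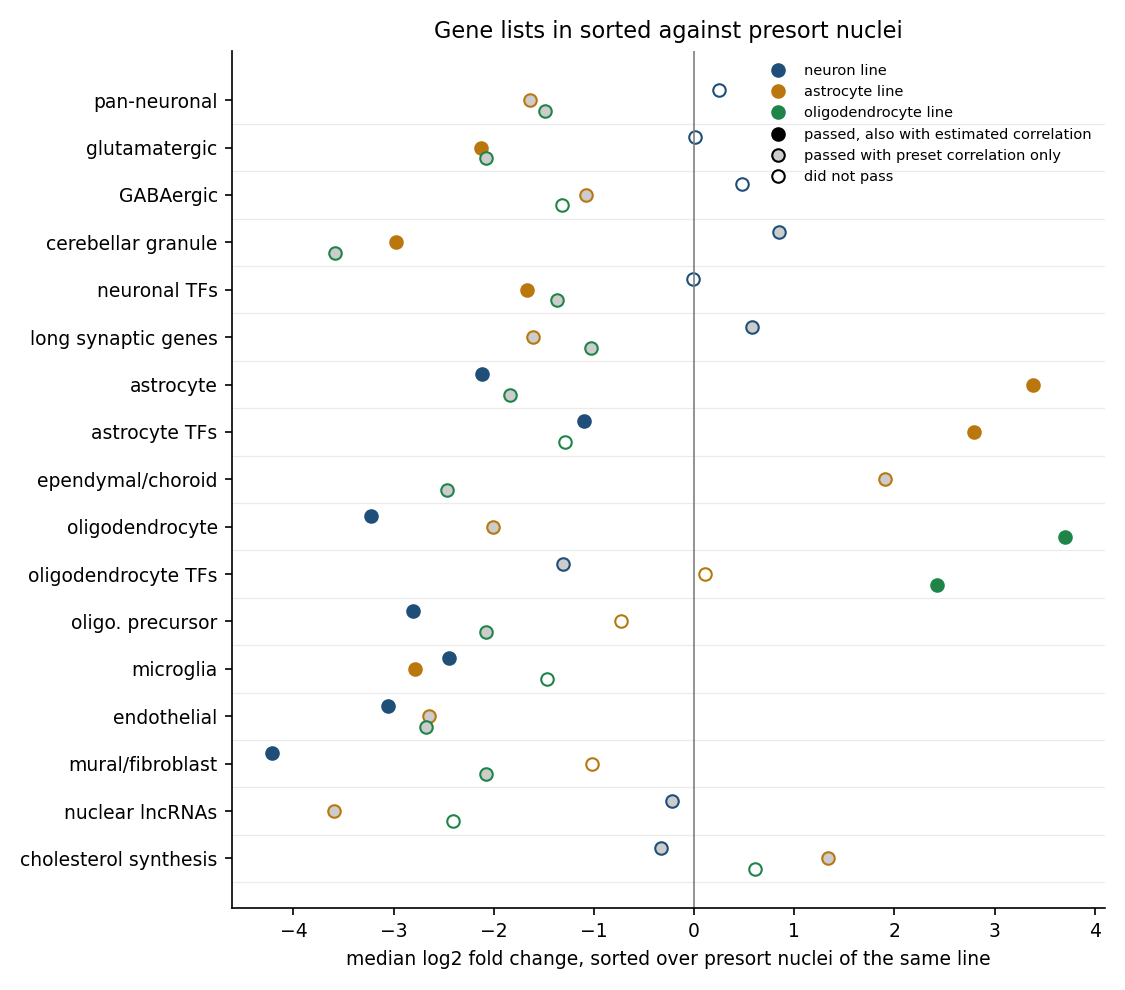
Median log2 fold change of each gene list in sorted over presort nuclei, with colour for the line and filling for the camera result (full colour where the call held with an estimated correlation in the fit without the block, grey where it passed with the preset correlation alone, white where it did not pass). The oligodendrocyte list lies at 3.70 in the oligodendrocyte line and at -3.22 in the neuron line, and the astrocyte list at 3.38 in the astrocyte line.

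In the astrocyte line, sorting raised astrocyte markers and lowered neuronal and microglial ones. All 27 astrocyte markers rose (27 adjusted over the list alone, median log2 fold change 3.38, camera adjusted p = 7.66e-23). Aqp4, the aquaporin of astrocyte endfeet, was at 1213 ± 290 against 71.9 ± 38.9 CPM (SD, n = 4 each, adjusted p = 8.71e-08). Fgfr3 (3.89 ± 0.31, SE), Gdf10 (3.91 ± 0.38) and Slc7a10 (3.80 ± 0.33) were others. All 13 tested astrocyte transcription factors rose (13 adjusted over the list alone, camera adjusted p = 6.5e-08), such as Hes5 (4.20 ± 0.58) and Rfx4 (3.83 ± 0.40). Cholesterol synthesis genes rose in 15 of 20 cases (16 adjusted over the list alone, camera adjusted p = 3.85e-07 and adjusted p = 0.172 with an estimated correlation), such as Msmo1 (2.41 ± 0.35) and Dhcr7 (2.25 ± 0.31). Ependymal and choroid plexus markers rose in 5 of 5 (5 adjusted over the list alone, camera adjusted p = 0.00987 and adjusted p = 0.218 with an estimated correlation), such as Ttr (3.03 ± 0.53) and Kl (1.91 ± 0.40). Gliosis genes rose in 4 of 6 cases (4 adjusted over the list alone, camera adjusted p = 0.0399), with Gfap at 2.16 ± 0.33. The gliosis list had adjusted p = 0.22 with an estimated correlation. Glutamatergic markers fell in 11 of 13 cases and 1 rose (11 and 1 adjusted over the list alone, camera adjusted p = 4.78e-05). Grin1 was at 87.2 ± 21.0 against 1482 ± 345 CPM (-4.02 ± 0.28, adjusted p = 9.45e-09). Granule cell markers fell in 7 of 9 cases and 1 rose (8 and 1 adjusted over the list alone, camera adjusted p = 1.97e-05), with Fat2 at -4.40 ± 0.27. Neuronal transcription factors fell in 13 of 17 (13 adjusted over the list alone, camera adjusted p = 6.41e-05). Pan-neuronal markers fell in 16 of 25 cases and 1 rose (18 and 1 adjusted over the list alone, camera adjusted p = 2.23e-07), such as Rbfox3 (-3.70 ± 0.34). The pan-neuronal list had adjusted p = 0.143 with an estimated correlation. Microglial markers fell in 9 of 11 cases (9 adjusted over the list alone, camera adjusted p = 3.51e-05). Endothelial markers fell in 10 of 14 while 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 4.68e-05), with Ptprb at -3.21 ± 0.48. The endothelial list had adjusted p = 0.157 with an estimated correlation. Meg3 (-4.65 ± 0.34) and Snhg11 (-4.25 ± 0.34) were among 5 nuclear lncRNAs of 8 that fell while 2 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.013). The lncRNA list had adjusted p = 0.318 with an estimated correlation.

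Some markers moved against their list in the astrocyte line. GABAergic markers fell in 4 of 9 cases while 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.02). The GABAergic list had adjusted p = 0.143 with an estimated correlation. Pdgfrb rose (log2 fold change 1.96 ± 0.34) while 4 of 10 mural and fibroblast markers fell (4 adjusted over the list alone, camera adjusted p = 0.136), such as Rgs5 (-3.39 ± 0.45), and Ptprz1 rose (2.96 ± 0.27) while Gpr17 fell (-4.65 ± 0.43). In the oligodendrocyte list 15 of 23 fell and 3 rose (15 and 3 adjusted over the list alone, camera adjusted p = 0.000125), with Mog at -3.17 ± 0.45. The oligodendrocyte list had adjusted p = 0.218 with an estimated correlation. In total 1514 genes were higher and 1679 lower of 11026 tested by edgeR (3010 of all tested genes not overlapping, 27.3%, against 2.86% by chance). Among the largest rises were those of Dao, the D-amino acid oxidase gene (4.94 ± 0.65), and Eva1a (4.82 ± 0.68). Among the largest falls, against 0 sorted counts, were those of Robo3, at least 43.3-fold, and Ptprc, a leukocyte antigen, at least 46.3-fold, or 26.6-fold and 28.4-fold without sorted astrocyte replicate 32. Aldh1l1 (3.36 ± 0.42, adjusted p = 3.58e-06), GFP (2.55 ± 0.33, adjusted p = 6.63e-06) and Rpl10a (1.93 ± 0.30, adjusted p = 4.61e-05) rose. Snap25 fell (-1.49 ± 0.35, adjusted p = 0.00215) and Cnp did not pass (-0.46 ± 0.30, adjusted p = 0.289). Males alone gave 726 higher and 802 lower genes, and females alone 1154 and 1448. Without presort replicate 29 the counts were 893 and 943, they were 948 and 1063 without sorted replicate 32 and 964 and 1039 without sorted replicate 8, and 1104 were lower without sorted replicate 6. The calls of the astrocyte, astrocyte transcription factor, glutamatergic, granule cell, neuronal transcription factor and microglia lists held with an estimated correlation, at adjusted p from 0.0397 to 0.047.

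In the oligodendrocyte line, 23 of 25 oligodendrocyte markers rose on sorting (24 adjusted over the list alone, median log2 fold change 3.70, camera adjusted p = 1.84e-28). The oligodendrocyte list had adjusted p = 0.000397 with an estimated correlation. Mobp reached 2992 ± 1443 against 134.7 ± 33.4 CPM (SD, n = 4 each, log2 fold change 4.47 ± 0.48, SE, adjusted p = 0.0013). Sox10 (5.13 ± 0.69), Fa2h (4.67 ± 0.60) and Hapln2 (4.42 ± 0.62) rose as well. Oligodendrocyte transcription factors rose in 7 of 11 cases (7 adjusted over the list alone, camera adjusted p = 1.26e-07), including Myrf (4.30 ± 0.59) and Zfp536 (3.55 ± 0.46). The oligodendrocyte factor list had adjusted p = 0.0179 with an estimated correlation. Neat1 (3.80 ± 0.55), Ptprd, a receptor phosphatase among the long synaptic genes (3.13 ± 0.37), and Zeb2 (2.87 ± 0.40) rose too. Granule cell markers fell in 7 of 8 cases (7 adjusted over the list alone, camera adjusted p = 9.92e-07), with Fat2 at -4.39 ± 0.52 and Cbln3 at -3.96 ± 0.60. The granule cell list had adjusted p = 0.123 with an estimated correlation. Pan-neuronal markers fell in 3 of 25 cases (8 adjusted over the list alone, camera adjusted p = 0.000196 and adjusted p = 0.415 with an estimated correlation). Astrocyte markers fell in 8 of 25 while 1 rose (13 and 1 adjusted over the list alone, camera adjusted p = 4.97e-06 and adjusted p = 0.394 with an estimated correlation). The lncRNAs Rian (-2.90 ± 0.45) and Snhg11 (-2.53 ± 0.42) fell. Endothelial markers fell in 1 of 13 cases (7 adjusted over the list alone, camera adjusted p = 0.000194), and Ttr fell (-2.46 ± 0.46). The endothelial list had adjusted p = 0.432 with an estimated correlation. Blood genes fell in 2 of 5 cases (4 adjusted over the list alone, camera adjusted p = 0.00797), but Hba and Hbb paralogs share sequence. The blood list had adjusted p = 0.415 with an estimated correlation.

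Of 9520 genes tested in the oligodendrocyte line 487 were higher and 308 lower by edgeR (2230 of all tested genes not overlapping, 23.4%, against 2.86% by chance), and 582 and 938 by DESeq2, a change from 61.3% to 38.3% higher. The median over all genes was -0.07, and with RLE factors -0.19. The largest rises were at least 19.4-fold for Fah, which encodes an enzyme of tyrosine breakdown, 20.6-fold for Tex52 and 10.9-fold for Slc7a15 against 0 presort counts, the last called in 1 of 4 refits that left out a presort library. Sh3bp2 kept its call in 0 of 4 such refits by edgeR, and Tesk2 and Sgsh, whose log2 fold changes of 6.42 ± 1.57 and 5.97 ± 1.62 were 2.61 and 2.22 without sorted replicate 36, kept theirs in 4 of 8 refits. Among the largest falls were those of Tpm2, at least 82.6-fold (54.3-fold without sorted replicate 34 or 10), with -5.29 ± 0.96 for Tbata, -5.11 ± 0.99 for Otx2 and -4.52 ± 0.86 for Grin2c, an NMDA receptor subunit. Cnp rose (3.06 ± 0.37, adjusted p = 0.00136). GFP (37.6 ± 25.8 against 62.0 ± 13.6 CPM, log2 fold change -0.71 ± 0.90, adjusted p = 0.725), Rpl10a (-0.75 ± 0.89, adjusted p = 0.7) and Aldh1l1 (-0.78 ± 0.79, adjusted p = 0.644) did not pass. Snap25 (-1.19 ± 0.51, adjusted p = 0.182) passed without sorted oligodendrocyte replicate 34 (-1.74, adjusted p = 0.0353). Males alone gave 1081 higher and 1070 lower genes, and females alone 0 and 0 by edgeR, with 694 genes at an unadjusted p under 0.05. The counts were 1031 and 1038 without sorted replicate 36, 212 and 55, 229 and 56, 226 and 76, and 226 and 90 without presort replicates 33, 35, 11 and 9, and 139 and 141 lower without sorted replicates 10 and 12.

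Presort nuclei and whole-brain cytoplasm differed in whole classes of transcripts. All 54 ribosomal protein genes were lower in nuclei (54 adjusted over the list alone, median log2 fold change -2.90, camera adjusted p = 1.84e-15 and adjusted p = 0.133 with an estimated correlation). Rpl38 was at 15.3 ± 10.9 CPM in 12 nuclear and 285 ± 74.4 in 2 cytoplasmic libraries (SD, log2 fold change -4.14 ± 0.42, SE, adjusted p = 1.09e-07). The size of this difference rested on cytoplasm replicate 2. Without it 31 of 53 ribosomal protein genes were lower and the median was -1.34, and Rps29 went from -4.41 to -1.25. Ribosomal protein genes made up 0.575% of the counts of cytoplasm replicate 1 and 3.01% of those of replicate 2, against a mean of 0.3234% in presort nuclei. Of the nuclear-encoded respiratory genes 53 of 54 were lower (53 adjusted over the list alone, median -2.85, camera adjusted p = 2.74e-16 and adjusted p = 0.0123 with an estimated correlation), with Cox6c at -3.95 ± 0.40 and Ndufa4 at -3.99 ± 0.40. All 10 mitochondrially encoded genes were lower (10 adjusted over the list alone, camera adjusted p = 8.59e-06), with mt-Nd1 at -5.07 ± 0.44, or -2.45 without cytoplasm replicate 1, when 8 of 10 were lower and the list median went from -4.88 to -2.52. The mitochondrial list had adjusted p = 0.328 with an estimated correlation. Mitochondrially encoded genes made up 5.89% of the counts of cytoplasm replicate 1 and 0.517% of those of replicate 2. Pan-neuronal markers were lower in nuclei in 20 of 25 cases and higher in 1 (20 and 1 adjusted over the list alone, camera adjusted p = 3.97e-08 and adjusted p = 0.00656 with an estimated correlation). They included Snap25 (-4.35 ± 0.33, adjusted p = 5.64e-09, or -2.95 without cytoplasm replicate 1). Neuronal transcription factors were lower in 13 of 17 cases (13 adjusted over the list alone, camera adjusted p = 0.000695 and adjusted p = 0.0878 with an estimated correlation). Nuclear lncRNAs were higher in nuclei in 7 of 8 cases (7 adjusted over the list alone, camera adjusted p = 5.71e-05 and adjusted p = 0.0922 with an estimated correlation), with Neat1 at 2.57 ± 0.37, and the list median of 2.37 was 4.97 without cytoplasm replicate 2. Over all lncRNA genes 58 of 96 were higher and 14 lower, against 1499 and 2252 of 7519 protein-coding genes. Endothelial markers were higher in nuclei in 14 of 15 cases (15 adjusted over the list alone, median 4.32, camera adjusted p = 8.59e-06 and adjusted p = 0.328 with an estimated correlation), with Ptprb at 5.78 ± 0.83. Mural and fibroblast markers were higher in 9 of 9 (9 adjusted over the list alone, camera adjusted p = 0.00255 and adjusted p = 0.344 with an estimated correlation), with Pdgfrb at 3.32 ± 0.60, and 6 of 9 were called without cytoplasm replicate 1.

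Other lists differed between nuclei and cytoplasm as well. Oligodendrocyte precursor markers were higher in nuclei in 6 of 8 cases (6 adjusted over the list alone, camera adjusted p = 0.00205), such as Vcan (log2 fold change 3.13 ± 0.35). The precursor list had adjusted p = 0.133 with an estimated correlation, and its median of 2.39 was 3.68 without cytoplasm replicate 2. Splicing factors were higher in 11 and lower in 5 of 24 cases (11 and 5 adjusted over the list alone, camera adjusted p = 0.0104 and adjusted p = 0.493 with an estimated correlation), such as Ccnl1 (2.90 ± 0.44) and Pnisr (2.35 ± 0.35). Without cytoplasm replicate 1 splicing factors were higher in 15 and lower in 0 cases by edgeR, and without replicate 2 in 9 and 8. Long synaptic genes were higher in 11 and lower in 4 of 23 (11 and 6 adjusted over the list alone, camera adjusted p = 0.0137 and adjusted p = 0.501 with an estimated correlation), such as Csmd3 (3.50 ± 0.47) and Grik2 (3.13 ± 0.33), with 1 lower without cytoplasm replicate 1 and 6 lower without replicate 2. Cbln3 (3.48 ± 0.52) was higher in nuclei in a granule cell list with 4 higher and 2 lower of 10 (4 and 2 adjusted over the list alone, camera adjusted p = 0.131). Glutamatergic markers were lower in 8 of 13 cases (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0401). The glutamatergic list had adjusted p = 0.133 with an estimated correlation. Among the largest differences, Ndufb6 (-5.88 ± 0.54) and Fam166a (-5.63 ± 0.53) were lower in nuclei. Cnp (-2.41 ± 0.36, adjusted p = 1.28e-05, or -1.70 without cytoplasm replicate 2) and Rpl10a (-1.08 ± 0.41, adjusted p = 0.034) were lower in nuclei, the latter not without cytoplasm replicate 2 (-0.02). Aldh1l1 (0.00 ± 0.59, adjusted p = 0.995, and 0.17 without cytoplasm replicate 2) and GFP (-0.62 ± 0.47, adjusted p = 0.29, and 0.57 without it) did not pass. By edgeR 1595 genes were higher and 2306 lower in nuclei of 7728 tested (2482 not overlapping, 32.1%, against 2.2% by chance), with 1200 and 1884 against the female presort libraries alone and 1034 and 1824 against the male ones. With 2 cytoplasmic libraries from different lines, prepared under another title scheme than the nuclei, preparation and compartment cannot be told apart. Cytoplasm replicate 1, the library labelled male, held 1 count over the 4 Y-linked genes (0.224 CPM), against 84.7 to 230 CPM in the 12 nuclear libraries of males and at most 0.381 CPM in the 12 of females.

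In sorted nuclei 2 genes were higher in females and 4 in males by edgeR, among them Xist and 4 Y-linked genes (57 of all tested genes not overlapping, 0.437%, against 0.216% by chance). DESeq2 gave 46 and 8, a change from 33.3% to 85.2% higher in females, and 34 and 8 passed by edgeR without the libraries that stood apart. Xist, the lncRNA of X inactivation (chromosome X from 103460366 to 103483254), reached 6912 ± 2049 CPM in 6 female and 8.65 ± 6.13 in 6 male libraries (SD; log2 fold change 9.73 ± 0.42, SE, adjusted p = 6.85e-09). The other gene higher in females was Gm26992 (9.27 ± 0.70, adjusted p = 5.94e-06), an unnamed model whose counts cannot be assigned to a strand. The 4 Y-linked genes were lower in females (4 adjusted over the list alone, median -8.98 as fitted and -7.18 with genes at 0 counts set at their bound, camera adjusted p = 1.19e-23). The Y-linked list had adjusted p = 0.00679 with an estimated correlation. Kdm5d and Ddx3y had 1 count each in females and were lower by count ratios of 1150 (95% counting interval 207 to 45600) and 215 (38.2 to 8520), or by at least 294-fold without sorted neuron replicate 28 and 53.7-fold without sorted astrocyte replicate 32, and Uty and Eif2s3y, with 0, were at least 172-fold and 88.8-fold lower. X-escape genes passed as a list with 1 of 5 higher, Xist (1 adjusted over the list alone, camera adjusted p = 1.82e-05 and adjusted p = 0.102 with an estimated correlation), and not without it (adjusted p = 0.321). Passing too were splicing factors, of which 0 of 24 passed by edgeR (0 adjusted over the list alone and 1 by DESeq2, median 0.18, camera adjusted p = 4.07e-05 and adjusted p = 0.186 with an estimated correlation). The nuclear lncRNA list, which holds Xist, passed with a median of -0.02 and a mean of 1.24 (1 of 8 higher, 1 adjusted over the list alone, camera adjusted p = 0.00379). The lncRNA list had adjusted p = 0.186 with an estimated correlation, and without Xist its adjusted p was 0.606.

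The mitochondrially encoded list moved up in females, a call lost in both fractions with an estimated correlation. In sorted nuclei its median log2 fold change was 1.80 (camera adjusted p = 2.2e-18 and adjusted p = 0.0622 with an estimated correlation), and 0 of 10 passed over all genes by edgeR, 5 by DESeq2 and 8 adjusted over the list alone. The difference in mean log2 CPM ranged from 0.098 to 1.781 among the 3 sorted types, with 4.252 and 4.038 in female against 4.199 and 3.895 in male astrocyte libraries. In presort nuclei the median was 1.196 (camera adjusted p = 2.39e-08 and adjusted p = 0.266 with an estimated correlation), and 3 of 8 passed (7 adjusted over the list alone). Among them were mt-Co1, a subunit of cytochrome c oxidase, at 1263 ± 463 CPM in 6 female and 447 ± 271 in 6 male libraries (SD, log2 fold change 1.57 ± 0.25, SE, adjusted p = 0.00435), and mt-Co3 (2.03 ± 0.36, adjusted p = 0.00772). In presort nuclei 54 genes were higher in females and 4 in males (113 of all tested genes not overlapping, 1.87%, against 0.216% by chance). After Xist (9.03 ± 0.36, adjusted p = 3.66e-12) and Gm26992, the genes with the smallest p included Hsp90b1, a chaperone of the endoplasmic reticulum (1.23 ± 0.18, adjusted p = 0.00353), and Tmx4 (1.24 ± 0.19). Others were Eif4a2 (1.37 ± 0.23), Slitrk4 (1.29 ± 0.22), Tgoln1 (1.21 ± 0.21), Gm26853 (1.35 ± 0.24), Hnrnpa3 (1.08 ± 0.19), Arl8b (1.45 ± 0.25) and Top2b (1.51 ± 0.27), all higher in females. Kdm5d was lower by a count ratio of 308 (95% counting interval 54.2 to 12300), or at least 28.1-fold without presort astrocyte-line replicate 29. X-escape genes were higher in 2 of 5 cases (3 adjusted over the list alone, camera adjusted p = 4.31e-06 and adjusted p = 0.0192 with an estimated correlation), and without Xist in 1 of 4 (adjusted p = 0.0136, and 0.263 with an estimated correlation). The ribosomal protein list moved down (0 of 32 over all genes by edgeR, 2 adjusted over the list alone and 1 by DESeq2, median -0.28, camera adjusted p = 0.0114 and adjusted p = 0.738 with an estimated correlation). Without the libraries that stood apart, 13 genes were higher in females and 2 in males among presort nuclei. Because males and females had separate blocks of title numbers, sex and a batch of libraries cannot be told apart in these comparisons.

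**Figure D4:**
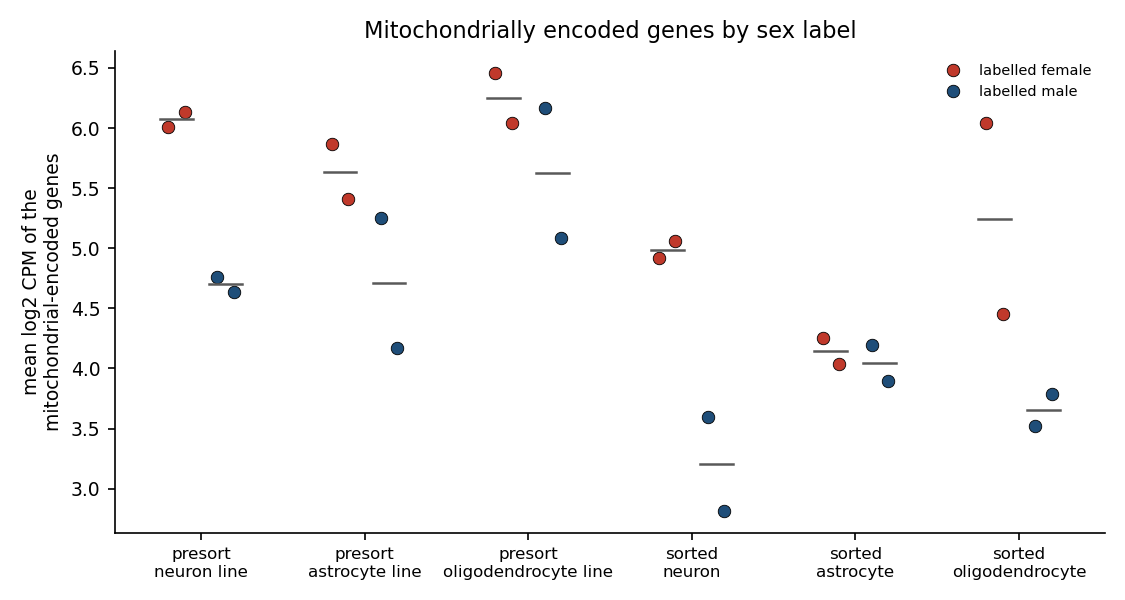
Mean log2 CPM of the mitochondrially encoded genes in each nuclear library, by fraction, line and sex label, with the mean of each sex as a line. In presort nuclei females averaged 5.99 and males 5.01, and in sorted nuclei 4.79 and 3.64.

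No gene passed the test for an interaction of sex and cell type in sorted nuclei by edgeR (0 of 13029, lowest adjusted p = 1, 272 at an unadjusted p under 0.05, and 0 by DESeq2). The simulated test recovered 43.8% of 64-fold changes. The smallest p was that of Oprm1, the mu opioid receptor gene, with a mean of 66.3 CPM in neurons, 7.02 in astrocytes and 203 in oligodendrocytes. Without a filter on low counts 86 genes passed.

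Presort nuclei of the 3 lines, which hold the same mixture of cells by their labels, gave 0 of 6049 genes by edgeR (205 at an unadjusted p under 0.05, 4 by DESeq2 and 1 without a filter). The lowest adjusted p by edgeR belonged to Cnp (adjusted p = 0.143), with mean values of 120.1 CPM in the astrocyte, 130.6 in the neuron and 289 in the oligodendrocyte line, and to GFP (adjusted p = 0.143), with 118, 246 and 83.6 CPM.

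Several lists passed in no comparison of sorted types or of sex. Between neurons and astrocytes 0 of 8 microglial markers passed by edgeR (0 adjusted over the list alone and 1 by DESeq2), with a median of 0.14, a mean of -0.18 and a camera direction of down (adjusted p = 0.868). Blood genes (median log2 fold change -0.46, camera adjusted p = 0.528) and host-gene lncRNAs (median 0.47, camera adjusted p = 0.396) had 0 of 5 and 0 of 4 members past the threshold there by edgeR, over all genes, over the list alone and by DESeq2. Of the modulatory neuron list 0 of 1 tested genes was enriched in a type.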

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

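The tests of GFP, of title numbers and of fewer vessel cells were chosen only after their results were seen. Among 66 sets of values tested for a library far from the others of its group, 7 had one, and chance alone marks about 1 in 20 groups. Presort astrocyte-line replicate 29 had 3274488 counts, against 147826 to 238420 in the other 3 libraries of its group. Sorted astrocyte replicate 30 had 11136 genes detected (others 16407 to 16516), and sorted oligodendrocyte replicate 36 had 7674 (others 16223 to 16575). Rpl10a was at 88.52 CPM in presort oligodendrocyte-line replicate 11 (others 49.79 to 54.19) and at 0 CPM in sorted oligodendrocyte replicate 36 (others 36.23 to 38.74), where 3 counts would be 1.872 CPM. Mitochondrially encoded genes took 0.3387% of the counts of sorted oligodendrocyte replicate 34 (others 0.0382% to 0.0585%), and the 10 highest genes took 8.172% of those of sorted neuron replicate 4 (others 7.546% to 7.651%).

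GFP and Rpl10a changed differently with sorting in the astrocyte and oligodendrocyte lines, by 3.143 ± 0.77 (log2, SE, edgeR adjusted p = 0.00484) and 2.598 ± 0.743 (adjusted p = 0.0168). GFP RNA was not higher in sorted than in presort nuclei of the oligodendrocyte line (-0.71 ± 0.90). One library of low complexity is argued against, since without sorted oligodendrocyte replicate 36 the log2 fold change of GFP was -0.285. A sort that did not select oligodendrocyte nuclei is argued against by the oligodendrocyte list, of which 23 of 25 genes rose. What stays open is a difference among the lines in how much of the fusion RNA is nuclear or in how the lines were sorted, which no value here tests and on which the sources used here say nothing.

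Mitochondrially encoded genes averaged higher in female libraries, with a mean log2 CPM of 5.988 against 5.013 in presort nuclei (difference 0.975, from 0.625 to 1.374 in the 3 lines) and 4.794 against 3.636 in sorted nuclei (difference 1.158, from 0.098 in astrocytes to 1.781, two-sided exact permutation p = 0.0185 in each, n = 6 against 6). The list lost its call with an estimated correlation in both fractions (adjusted p = 0.266 and 0.0622), and 0 of 10 of its genes passed by edgeR in sorted nuclei (5 by DESeq2). More cytoplasmic RNA carried along with the female nuclei would raise other cytoplasmic genes as well, and the score of 2296 cytoplasm-high over 1594 nucleus-high genes was -0.06 in presort females minus males (from -0.231 to 0.121 in the lines, exact permutation p = 0.583), too wide a spread to decide. A batch of libraries cannot be told apart from sex, because 0 blocks of title numbers held both sexes. Sex itself, a biological difference that the labels give, stays open and untested for the same reason.

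Endothelial and mural genes were higher in presort nuclei than in cytoplasm in 23 of 24 cases. A gain of nuclear counts in long genes is argued against, because the list median of 3.637 lay at percentile 100 of 10000 random lists matched on gene span and expression, whose highest median was 1.369. Fewer blood vessel cells in the cytoplasmic libraries may be the cause, and the same 23 genes are what it needs, but they are also what defined the pattern. With 2 cytoplasmic libraries that explanation and a nuclear excess within vessel cells cannot be told apart, and no biological explanation was tested.

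Other splits made chance unlikely for the sorted types and, in presort nuclei, for the split by sex label and title numbers together. The labelled split alone gave as many genes (1 of 35 splits) for neurons against astrocytes (2534, highest other 0), neurons against oligodendrocytes (3005, highest other 1) and astrocytes against oligodendrocytes (2230, highest other 1). For sorted against presort nuclei each mouse gave both, per the design text, and 8 splits part all 4 pairs of neighbouring numbers, too few for a share under 0.05. The labelled split gave 702 genes in the neuron, 3193 in the astrocyte and 795 in the oligodendrocyte line (highest other 0 in each). Splits that keep a pair together gave at most 85, by sex, 4 and 2. Of 100 splits 1 gave as many enriched genes in neurons (679), astrocytes (758) and oligodendrocytes (698), with 423 as the highest other. For sex 1 of 100 splits gave as many in sorted (6, highest other 0) and in presort nuclei (58, highest other 1). The interaction (0, highest other 4) and the lines (0, highest other 3) gave no genes, which 100 of 100 splits reach whatever the grouping, so the splits decide nothing there.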

How the results depend on the processing

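Fits of each sex alone, of presort libraries of each sex against cytoplasm, and without the 3 libraries that stood apart, gene lists without each cytoplasmic library or without Xist, and count bounds without each library, were chosen after seeing the data. Counts are given as higher and lower genes in the order of each comparison. Of 360 alternative counts 234 stayed within 1.5 times the reported one and 126 moved. Among named genes 5339 alternative values kept their direction and side of the threshold, 289 lost the call, 9 gained one and 12 changed sign. Among gene lists 376 alternative results kept their side of the threshold, 85 lost the call, 78 of them with an estimated correlation and 7 with ranks, and 11 gained one with ranks. The direction of lists was not compared. The causes of the moves below were not tested, except where fewer libraries or counts are the alternative itself.

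DESeq2 gave 2288 higher for neurons against oligodendrocytes, 1031 neuron-enriched genes, 252 higher in the neuron-line sort, 938 lower in the oligodendrocyte-line sort, 46 higher in females and 8 in males among sorted nuclei, 105 and 21 among presort nuclei, and 4 among the lines. RLE factors gave 35 higher in presort females. Sex as a covariate gave 408 higher in the neuron-line sort.

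Thinning to the smallest library, which removes counts, gave 491 and 592 for neurons against astrocytes, 611 and 647 for neurons against oligodendrocytes and 572 and 499 for astrocytes against oligodendrocytes. Enriched genes were 320, 345 and 346 in neurons, astrocytes and oligodendrocytes. The sort gave 60 and 226 in the neuron line and 613 and 603 in the astrocyte line, nuclei against cytoplasm 1006 and 1258, and sex 1 higher in males among sorted nuclei and 13 in females and 1 in males among presort nuclei.

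Without a filter on low counts the sort gave 383 higher in the neuron line, 2558 lower in the astrocyte line and 839 higher in the oligodendrocyte line. Nuclei against cytoplasm gave 2617 and 4198, sex 23 and 7 in sorted and 111 and 18 in presort nuclei, the interaction 86 and the lines 1. A fit of all 24 nuclear libraries gave 1663 higher for neurons against astrocytes, 1834 lower for astrocytes against oligodendrocytes, 1062 neuron-enriched and 1221 oligodendrocyte-enriched genes. In it the sort gave 17 higher in the neuron line, 816 higher in the astrocyte line and 1513 and 1552 in the oligodendrocyte line.

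The replicate block gave 546 and 904 in the neuron line, 222 and 59 in the oligodendrocyte line and 1366 and 1607 in the astrocyte line. That neighbouring numbers are 1 mouse was inferred, and the pairs correlated most in the neuron line. In that line 7 lists lost their call under the block with an estimated correlation, and the mitochondrially encoded list gained one with the preset correlation. Sorted nuclei against cytoplasm gave 458 and 1273, and male presort nuclei against cytoplasm 1034 higher.

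Without the 3 libraries that stood apart the counts were 2156 and 2745 for neurons against astrocytes, 2298 and 2549 for neurons against oligodendrocytes, 1927 and 1481 for astrocytes against oligodendrocytes, and 1220 neuron-enriched and 1252 astrocyte-enriched genes. The oligodendrocyte-line sort gave 1031 and 1038, and sex 34 and 8 in sorted and 13 and 2 in presort nuclei.

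Males alone gave 1627 higher for neurons against astrocytes, and in the sort 0 and 127 in the neuron, 726 and 802 in the astrocyte and 1081 and 1070 in the oligodendrocyte line. Females alone, among them the shallowest sorted library and the one with the fewest genes, gave 8 and 38 for neurons against astrocytes, 9 and 114 for neurons against oligodendrocytes, 17 and 50 for astrocytes against oligodendrocytes, 6, 9 and 32 enriched genes, 241 higher in the neuron-line sort, and 0 and 0 in the oligodendrocyte-line sort by edgeR (694 at an unadjusted p under 0.05).

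Leaving out 1 library at a time gave 684 to 2299 and 1177 to 2797 for neurons against astrocytes, 1099 to 2263 and 1214 to 2544 for neurons against oligodendrocytes, and 990 to 1980 and 715 to 1588 for astrocytes against oligodendrocytes. Enriched genes ranged from 493 to 1247 in neurons, 581 to 1282 in astrocytes and 547 to 969 in oligodendrocytes. The sort ranged from 45 to 262 and 297 to 789 in the neuron line, 893 to 1847 and 943 to 1841 in the astrocyte line, and 212 to 1031 and 55 to 1038 in the oligodendrocyte line. Nuclei against cytoplasm ranged from 1919 to 2136 and 2196 to 2403, where the lone cytoplasmic library was assumed to vary like the other groups, and the lines stayed at 0.

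Of the genes whose log2 fold change changed sign, none had passed in the reported fit except Cnp and Rpl10a in nuclei against cytoplasm. Without 1 library at a time GFP was at -0.4631 to 0.0974 for neurons against astrocytes, the latter without sorted astrocyte replicate 6. Aldh1l1 in sorted neuron vs sorted oligodendrocyte, males only, was at 0.0779, and it was at 0.0047 in the oligodendrocyte-line sort in females, and at 0.0891 with DESeq2 and 0.0874 with RLE factors for sex in sorted nuclei. For nuclei against cytoplasm Aldh1l1 was at 0.3615 with the 8 presort libraries of the astrocyte and oligodendrocyte lines, at -0.0772 without cytoplasm replicate 1 and at 0.1697 without replicate 2. GFP was at -1.1665 and 0.5698 without these. With sorted libraries as the nuclear side, Aldh1l1 in presort nuclei vs cytoplasm was at 2.4687 and Rpl10a in presort nuclei vs cytoplasm at 0.0431, with GFP at 1.1069 and Cnp at 0.0235. The main depth limit was in presort nuclei, with a median of 260451 counts against 2485416.5 in sorted nuclei.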

Other observations

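Ependymal and choroid plexus genes summed to 7122.8, 6386.6 and 4825.7 CPM in sorted astrocyte replicates 30, 32 and 8. Replicate 6 held 605.8, against 392.4 to 1010.8 in presort libraries of the line and at most 173.2 in other sorted types. Folr1, Clic6, Kl and Ttr were enriched over both other types. Of the nuclear lncRNA list Meg3, Mirg, Rian and Snhg11 were enriched in neuron nuclei, although the list did not pass against either other type. The granule cell genes Gabra6, Cbln1 and Fat2 were enriched as well. Within the neuron line Meg3 nevertheless fell on sorting (log2 fold change -1.05 ± 0.18, SE, edgeR).

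Cytoplasm replicates 1 and 2 differed in several measures. Snap25 was at 11412 and 3497 CPM, Meg3 at 161 and 2599 CPM, mitochondrially encoded genes at 5.89% and 0.517% of counts and ribosomal protein genes at 0.575% and 3.01%. Cytoplasm replicate 1, the library labelled male, had 0 counts of Eif2s3y beside 1185 of Eif2s3x, and replicate 2, labelled female, 0 and 385, whereas the ratio of Eif2s3y to Eif2s3x was 0.287 to 1.83 in the 12 nuclear libraries of males. The 12 nuclear libraries of males held 22 to 590 counts over the 4 Y-linked genes, and the 12 of females 0 or 1.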
